A study of Homo sapiens with 6 samples.

How the data were processed

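RNA was sequenced from NB-4 cells in 2 groups of 3 libraries, treated for 48 h with DMSO or with importazole at 5 µM. Per the labels' protocols, total RNA was extracted with a column kit, reverse-transcribed and amplified by the Geo-seq method, which was made for very small inputs, and turned into libraries with a transposase-based kit. Amplified libraries without molecular identifiers hold PCR copies, so reads are not independent molecules. The groups were taken from the sample titles.

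The deposited table held raw counts per gene, as whole numbers, with no normalization by the authors seen in the values. Per the submitters' processing notes, the tools were Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2, with no stated role or order, and the genome build was the mouse build mm10. That build contradicts the table, in which all 20263 identifiers were human Ensembl gene identifiers. The human build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain in how their reads were assigned. Symbols came from a table of gene names, which matched 20148 identifiers. Positions, transcript lengths, GC content and exon overlaps came from GENCODE release 29 on GRCh38, which matched 20224 identifiers, and 5320 of the identifiers had exons that overlap those of another listed gene.

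The libraries held 25068847 to 40216282 counts. Pairs of libraries within a group differed by a chi-square of 23.6 to 283 per degree of freedom over genes with at least 20 pooled counts, far above sampling noise, so no library was taken as a repeat deposit of another. CPM values were computed from the deposited counts with TMM-scaled library sizes.

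The comparison used edgeR 4.0.16 in R 4.3.3, with TMM factors, edgeR's default filter on low counts by group, which kept 12566 genes, and the quasi-likelihood F test on treatment alone with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. There were 30 lists with 1017 symbols, of which 968 were in the table, and each list had at least 5 tested members. A member was counted as risen or fallen over all genes tested and, separately, adjusted over the list alone. The lists, the tests and most alternatives were fixed before the data were examined.

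The rule for named genes was also fixed then. It takes KPNB1; up to 12 genes per direction with the largest change among genes with a symbol that passed the threshold, had a mean CPM of at least 5 and showed no overlap between the groups; and in each list up to 4 members with the lowest p and a mean CPM of at least 1. Of the 8 called genes, 5 met the part of the rule on called genes and H2BC9 was named by its list. Other genes named were chosen after their values were seen: ENSG00000272772, ENSG00000257065, list members named beyond the 4 because they passed over their list alone, and the genes that open the last part of the closing section.

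Alternatives were RLE, upper quartile and library size scaling, no filter, a filter at a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of mitochondrially encoded and ribosomal protein genes, and leaving out each library in turn. Added after seeing the data were robust edgeR, limma with a quality weight per library, and a correction that removed each library's smooth trend with transcript length and GC (mgcv 1.9.3; 99.9% of tested genes had both values). Quality weights ranged from 0.117 for DMSO replicate 3 to 3.21 for DMSO replicate 1. With DMSO replicate 2 at 0.512, the DMSO mean in that fit rests mostly on DMSO replicate 1. Counts of calls from that fit are to be read with this limit.

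The tests were checked on simulated counts drawn from the means, depths and spread of these libraries, with 200 changed genes. At the spread of all 6 libraries, edgeR on 12457 genes recovered 36% of genes changed by a log2 of 1 and 95% of those changed by a log2 of 2, with 13 false calls. At the spread without DMSO replicate 3, on 12478 genes, it recovered 74% and 99%, with 11 false calls. At the spread of all 6, a 2-fold change was thus missed more often than it was called. The changed genes were drawn only from genes above a minimum mean count, so these shares do not cover the lowest genes. Genes were drawn independently, without the joint shift of DMSO replicate 3.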

Results

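Gene expression was measured by RNA sequencing in NB-4 cells, an established human line of acute promyelocytic leukaemia. The cells had been kept for 48 h with importazole (IPZ) at 5 µM or with its solvent DMSO. Importazole is a small molecule that inhibits importin β1, the nuclear import receptor encoded by KPNB1, and the study asked how this inhibition alters gene expression. Each group held 3 libraries. The table gave raw read counts for 20263 genes, and the libraries summed to 38720980, 40186020 and 34319318 counts for DMSO replicates 1 to 3 and to 40216282, 25068847 and 36342559 for IPZ replicates 1 to 3. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

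KPNB1 itself (ENSG00000108424, chromosome 17, 47649476 to 47685505; all positions are those of GENCODE release 29 on GRCh38) showed no detectable difference in mRNA level. It stood at 454 ± 90 CPM (counts scaled to a common library size; mean ± SD, n = 3) with DMSO and at 483 ± 21.6 (SD, n = 3) with importazole. The log2 fold change was 0.09 (SE 0.17; adjusted p = 0.757, edgeR quasi-likelihood test), and its sign turned to negative without DMSO replicate 3, with quality weights and after a correction for length and GC. Since the compound acts on the protein, the mRNA level does not check the labels.

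DMSO replicate 3 stood apart from the other 5 libraries on the first principal component, which held 57.5% of the variance. It lay at -80.0, the other DMSO libraries at -7.83 and 12.1 and the IPZ libraries from 18.7 to 33.5. Cytosolic ribosomal protein genes took 15.1% of its counts and 8.39% to 10.1% of those of the other libraries. Its Spearman correlations with the others were 0.964 to 0.976, against 0.981 to 0.986 among the other 5. Across genes, which are not independent replicates, its deviation from the median of the other libraries correlated with transcript length (Spearman rho = -0.55) and with GC content (rho = 0.51). The rho with length was -0.31 in DMSO replicate 1, 0.10 in DMSO replicate 2 and 0.19 to 0.27 in the IPZ libraries.

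**Figure D1:**
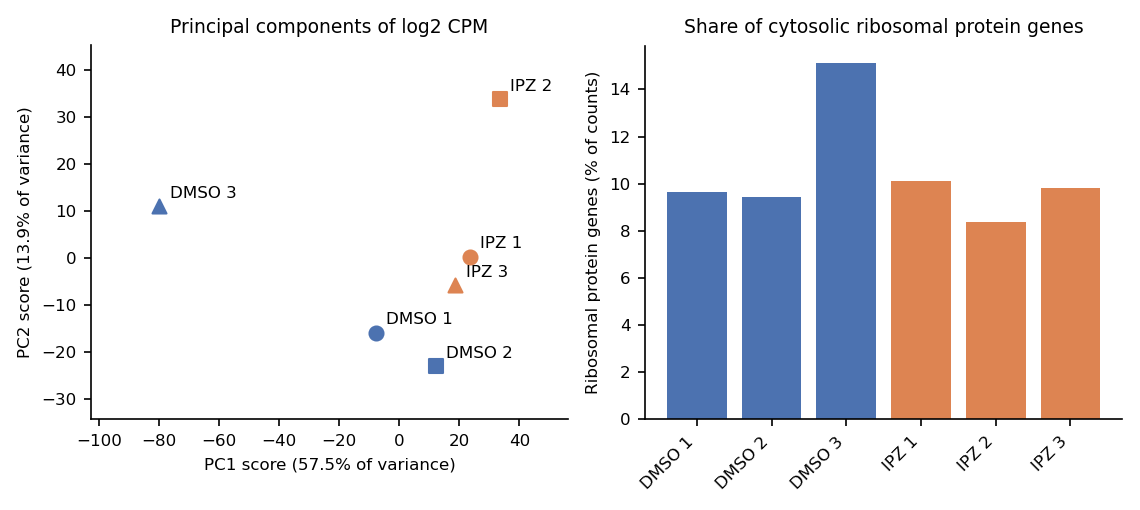
Left, scores of the 6 libraries on the first and second principal components of log2 CPM, coloured by group (blue DMSO, orange IPZ) with the replicate as the marker shape; DMSO replicate 3 lies at -80.0 on the first component and the others between -7.83 and 33.5. Right, bars give the share of each library's counts from cytosolic ribosomal protein genes in percent, highest in DMSO replicate 3 at 15.1%.

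Few single genes differed between importazole and DMSO past the threshold, but some of these by large folds with little spread within groups. PTPRN2, which encodes a phosphatase-like membrane protein of secretory vesicles, fell from 151 ± 6.33 to 25.1 ± 2.83 CPM (SD, n = 3 each). BCL2L2, which encodes the anti-apoptotic protein BCL-w, fell from 29.7 ± 3.22 to 2.82 ± 0.477 CPM. MEX3C, an RNA-binding ubiquitin ligase, rose from 6.88 ± 3.08 to 69.3 ± 0.732 CPM. Complement component C3 rose from 12.4 ± 0.815 to 47.4 ± 7.05 CPM, and NCK2, an adaptor protein of tyrosine kinase signalling, from 17.9 ± 1.19 to 52.2 ± 4.42 CPM. In all 5 genes the 3 IPZ libraries lay entirely on one side of the 3 DMSO libraries.

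These 5 genes met the rule for naming called genes that was fixed before the data were examined. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12566 genes, the log2 fold change was -2.59 for PTPRN2 (SE 0.14; adjusted p = 0.00227), -3.39 for BCL2L2 (SE 0.20; adjusted p = 0.00227) and 3.33 for MEX3C (SE 0.34; adjusted p = 0.0401). It was 1.94 for C3 (SE 0.16; adjusted p = 0.0133) and 1.54 for NCK2 (SE 0.14; adjusted p = 0.0177). PTPRN2 (ENSG00000155093) lies on chromosome 7 at 157539056 to 158587788 and BCL2L2 (ENSG00000129473) on chromosome 14 at 23298790 to 23311759. MEX3C (ENSG00000176624) lies on chromosome 18 at 51174550 to 51218304, C3 (ENSG00000125730) on chromosome 19 at 6677704 to 6730562 and NCK2 (ENSG00000071051) on chromosome 2 at 105744897 to 105894274. Exons of BCL2L2 overlap those of PPP1R3E and of the read-through gene BCL2L2-PABPN1, and whether the counting used strand is not given in the sources used here.

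The remaining 3 called genes did not meet that part of the rule. H2BC9 is named through the histone list, and the entries with no symbol were chosen after their values were seen. H2BC9 (ENSG00000275713, chromosome 6, 26251651 to 26253710), a histone H2B gene of a family of near-identical copies and so uncertain in its read assignment, rose from 0.793 ± 0.225 to 7.80 ± 0.365 CPM (SD, n = 3; log2 fold change 3.30, SE 0.26; edgeR adjusted p = 0.0114). ENSG00000272772 (chromosome 5, 134167170 to 134226071), an entry with no symbol whose exons overlap those of SKP1 and PPP2CA, rose from 1.55 ± 0.219 to 36.8 ± 2.40 CPM (log2 fold change 4.56, SE 0.18; edgeR adjusted p = 5.31e-04). ENSG00000257065 (chromosome 6, 143807092 to 143844617), whose exons overlap those of PHACTR2 and LTV1, fell from 6.34 ± 2.82 to 0.0300 ± 0.00832 CPM (edgeR adjusted p = 0.0114). It held 733 counts over the DMSO libraries and 3 over the IPZ libraries, a ratio per unit depth of 231 (95% exact interval 78.8 to 1124, which covers counting error only).

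**Figure D2:**
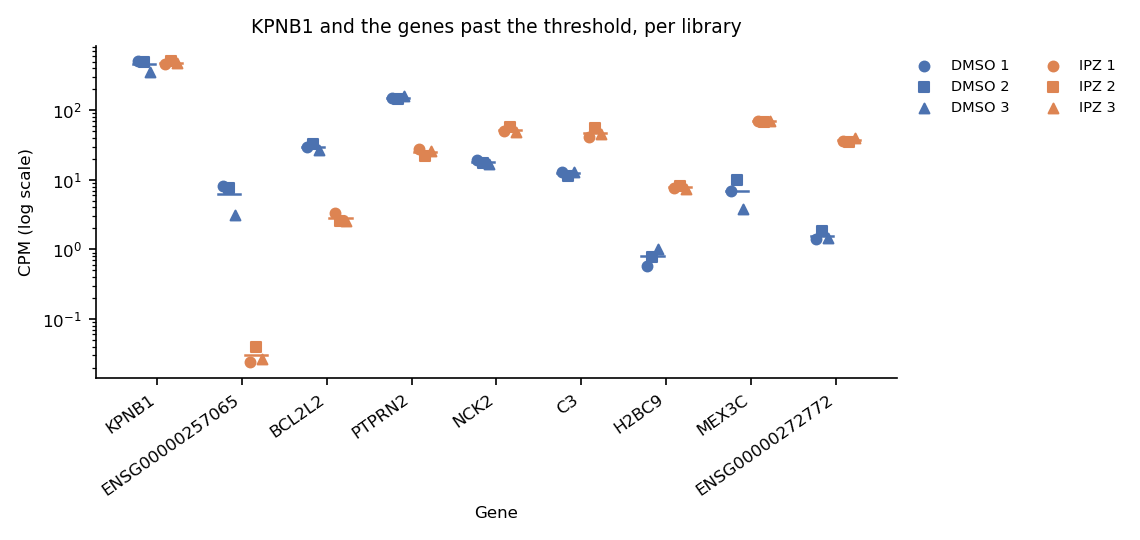
CPM per library on a log scale for KPNB1 and the 8 genes past the adjusted p threshold of 0.05; each point is a library (blue DMSO, orange IPZ, marker shape by replicate) and each short line the mean of its group. The DMSO and IPZ points overlap for KPNB1 and for none of the 8 genes.

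In total 8 genes passed an adjusted p of 0.05, of which 5 rose and 3 fell, each by at least 2-fold. An unadjusted edgeR p under 0.05 was reached by 1382 genes. With a library left out, that number ranged from 549 (without IPZ replicate 2) to 3563 (without DMSO replicate 2). With scaling by library size alone the 8 calls were 4 up and 4 down, and MEX3C was not among them. MEX3C also lost its call with the filter at a mean CPM of at least 5 (edgeR adjusted p = 0.0586). DESeq2 called 135 genes, 51 up and 84 down, and the 8 were all among them. Without DMSO replicate 3, edgeR called 20 genes, 10 up and 10 down, again with the 8 among them. BCL2L2, PTPRN2 and ENSG00000272772 stayed called when each of the 6 libraries was left out in turn, while the other 5 each lost the call in at least 3 of these 6 fits. H2BC9 and ENSG00000257065 lost it without each IPZ library, C3 and MEX3C also without DMSO replicate 1, and NCK2 without any library other than DMSO replicate 3. The highest edgeR adjusted p over all alternatives lay between 0.0886 for H2BC9 and 0.230 for MEX3C among these 5 genes, and no fit turned a direction.

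Genes of the hypoxia response and of glycolysis lay lower after importazole. Of 30 list members tested, 17 fell when adjusted over the list alone, and the median log2 fold change was -0.62 (camera adjusted p = 1.07e-11; adjusted p = 0.101 with an estimated correlation). ALDOC, a glycolytic aldolase, went from 69.7 ± 16.6 to 21.5 ± 1.08 CPM (SD, n = 3; log2 fold change -1.69, SE 0.20). BNIP3, a mitophagy receptor induced in hypoxia, went from 236 ± 17.5 to 118 ± 11.97 CPM, PFKFB4, a regulator of glycolytic flux, from 39.6 ± 6.26 to 18.3 ± 2.095 CPM, and NDRG1, a stress-induced gene, from 63.6 ± 5.20 to 35.5 ± 2.34 CPM. Those 4 passed when adjusted over the list alone, and the glycolytic enzymes ENO1, ALDOA, PGK1, PKM, TPI1 and GPI did so as well. Over all genes tested, edgeR called 0 of the 30, of which 17 had an unadjusted p under 0.05; limma-voom called 0, DESeq2 7 and limma with quality weights 16. The list lay 0.68 higher in DMSO replicate 3 than in the median of the other 5 libraries. These include the 3 IPZ libraries, so this offset, like those given for lists below, can also hold part of any treatment difference. Without DMSO replicate 3 the list's median was -0.45, with 21 members fallen when adjusted over the list alone. That count was 11, 7 and 6 without IPZ replicates 1, 2 and 3, and ALDOC, BNIP3, PFKFB4, NDRG1, GPI and CA9 passed with each library left out in turn.

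**Figure D3:**
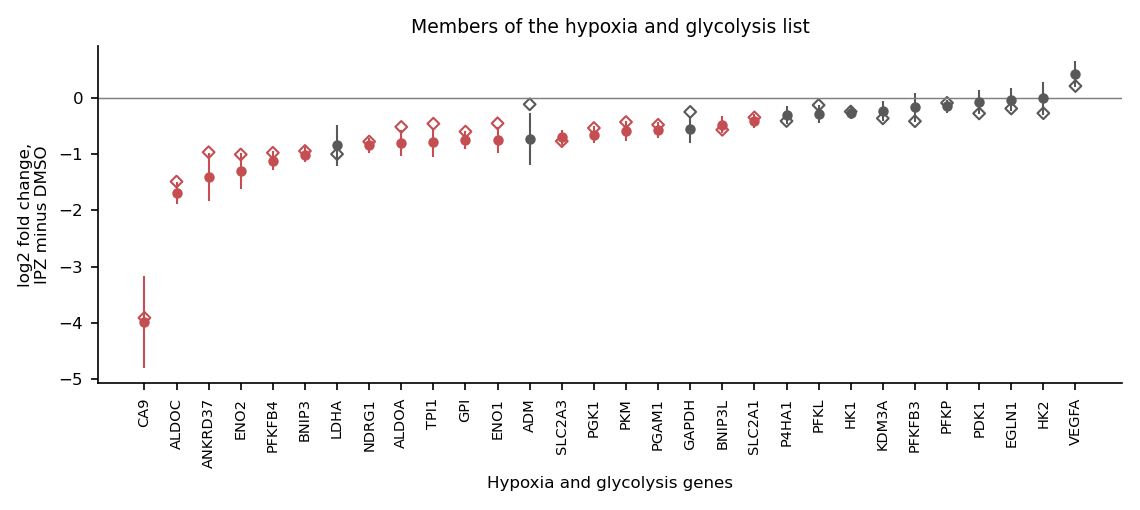
Log2 fold change (IPZ minus DMSO) of the 30 tested members of the hypoxia and glycolysis list, as filled points with the standard error, red where the adjusted p over the list alone was under 0.05; open diamonds give the value without DMSO replicate 3. The 17 red points all lie below 0.

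Cholesterol synthesis genes also lay lower, with a median log2 fold change of -0.47 over 28 members (camera adjusted p = 1.02e-06; adjusted p = 0.101 with an estimated correlation). Adjusted over the list alone, 8 fell. They included MSMO1 and IDI1, enzymes of the sterol pathway, at 14.2 ± 0.729 against 6.84 ± 0.538 CPM and 25.3 ± 0.806 against 16.9 ± 0.363 CPM (SD, n = 3; DMSO against IPZ). INSIG1, a sterol-sensing regulator, stood at 68.8 ± 7.48 against 38.3 ± 9.03 CPM, and FDFT1, squalene synthase, at 136 ± 20.1 against 90.1 ± 2.98 CPM. edgeR called 0 of the 28 over all genes tested, 11 with an unadjusted p under 0.05; limma-voom called 0, DESeq2 3 and limma with quality weights 10. The list lay 0.44 higher in DMSO replicate 3, and its median was -0.33 without that library, with 12 members fallen when adjusted over the list alone, and -0.30 with quality weights. That count was 1 without DMSO replicate 1 or IPZ replicate 2 and 0 without IPZ replicate 1 or 3.

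Stress-response genes under ATF4 and the unfolded protein response lay higher as a list, with a median of 0.19 over 41 members (camera adjusted p = 4.64e-04; adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell. HSPA5, the endoplasmic reticulum chaperone BiP, rose from 718 ± 30.1 to 1081 ± 37.4 CPM (SD, n = 3), PSAT1, a serine synthesis enzyme, from 70.0 ± 3.07 to 110 ± 7.84 CPM, and ALDH1L2, a mitochondrial folate enzyme, from 10.2 ± 4.04 to 31.5 ± 5.18 CPM. DDIT4, an inhibitor of mTOR signalling, was the member that fell, from 90.3 ± 25.9 to 37.3 ± 9.07 CPM. Over all genes tested, edgeR and limma-voom called 0 of the 41, of which 9 higher and 1 lower had an unadjusted edgeR p under 0.05, while DESeq2 called 3 up and 1 down and limma with quality weights 9 up and 1 down. Over the list alone no member passed without any one of the IPZ libraries, and 2 rose without DMSO replicate 1. Without DMSO replicate 3, 10 rose over the list alone and 15 lay higher at an unadjusted p under 0.05.

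Interferon-stimulated genes lay higher as a list, with a median of 0.34 over 36 members, 27 of them above 0 (camera adjusted p = 3.28e-04; adjusted p = 0.101 with an estimated correlation). No single member passed: edgeR called 0 adjusted over the list alone and 0 over all genes, with 9 at an unadjusted p under 0.05, while limma-voom and DESeq2 called 0 over all genes and limma with quality weights 7. Without DMSO replicate 2, 5 members rose when adjusted over the list alone. SAMD9L stood at 3.93 ± 1.57 with DMSO and 8.67 ± 0.314 CPM with importazole (SD, n = 3), and EIF2AK2, the RNA-activated kinase PKR, at 56.4 ± 16.2 and 91.6 ± 8.09 CPM. The list lay lower in DMSO replicate 3 than in the other libraries, by -0.43.

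Immediate early genes lay lower, with a median of -0.34 over 28 members (camera adjusted p = 3.28e-04; adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone, 4 fell. The transcription factor genes were JUN, at 31.0 ± 2.62 against 18.9 ± 1.03 CPM (SD, n = 3; DMSO against IPZ), EGR2, at 1.76 ± 0.349 against 0.643 ± 0.105 CPM, KLF2 and KLF4. The camera call ended with the filter at a mean CPM of at least 5 (adjusted p = 0.0712, from 1.68e-06 to 0.0712 over the 17 alternatives), and the median was -0.18 after the correction for length and GC. Over the list alone 0 members fell without DMSO replicate 2, IPZ replicate 1 or IPZ replicate 3, 2 without DMSO replicate 1 and 6 without DMSO replicate 3.

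Among lists of blood cell identity, the azurophil granule genes, which promyelocytes such as NB-4 express, lay lower with a median of -0.54 over 17 members (camera adjusted p = 1.08e-05; adjusted p = 0.306 with an estimated correlation). Adjusted over the list alone, 3 of its members fell: MS4A3, RNASE3 and SERPINB10. Membership is that of the list as fixed, and whether each member encodes a granule protein was not checked. MS4A3 went from 43.8 ± 3.07 to 28.9 ± 1.10 CPM (SD, n = 3). This list lay 1.00 higher in DMSO replicate 3 than in the other libraries, and its median was -0.22 without that library (with 5 members fallen adjusted over the list alone), -0.23 with quality weights and -0.17 after the correction for length and GC. Over the list alone 0 members fell without DMSO replicate 1 or any one of the IPZ libraries. Monocyte and macrophage genes had a median of -0.26 over 19 members (camera adjusted p = 0.0225, and 0.223 with an estimated correlation). Of these FCN1, IRF5 and CCR2 fell when adjusted over the list alone, and only CCR2 did so with each library left out in turn. CCR2 was low in counts, at 1.08 ± 0.301 with DMSO and 0.149 ± 0.0353 CPM with importazole (SD, n = 3). Its mean CPM of 0.613 is under the floor of 1 set for naming list members, and its edgeR adjusted p over all genes was 0.113. The monocyte list lay 0.38 higher in DMSO replicate 3, and its median was -0.38 without that library, -0.16 with library size scaling and -0.45 with the filter at a mean CPM of at least 5. FCN1, a pattern-recognition lectin, stood at 18.1 ± 4.60 with DMSO and 8.80 ± 0.688 CPM with importazole. Lymphoid markers, listed as genes of another cell type, had a median of -0.66 over 8 members (camera adjusted p = 0.00505; adjusted p = 0.306 with an estimated correlation), with IGHM and TRAC fallen when adjusted over the list alone. They lay 0.96 higher in DMSO replicate 3, and their median was -0.22 without it and -0.42 with quality weights. The correction for length and GC ended the calls of the monocyte and lymphoid lists (adjusted p = 0.0613 for both), with medians of -0.21 and -0.36.

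Nuclear-encoded oxidative phosphorylation genes and cytosolic ribosomal protein genes lay lower as lists after importazole, and lay 0.97 and 0.95 higher in DMSO replicate 3 than in the other libraries. The oxidative phosphorylation list had a median of -0.57 over 75 members (camera adjusted p = 2.10e-13; adjusted p = 0.525 with an estimated correlation), and -0.25 both without DMSO replicate 3 and with quality weights. Without that library 70 of the 75 members lay below 0 and the list still passed camera (adjusted p = 3.75e-12, from 1.44e-17 to 4.70e-08 over 17 alternatives; adjusted p = 0.410 with an estimated correlation). edgeR called 0 of its members adjusted over the list alone or over all genes, 27 lower and 1 higher with an unadjusted p under 0.05 (13 and 2 without DMSO replicate 3). DESeq2 called 1 up and 1 down over all genes, limma-voom 0 and limma with quality weights 1 up and 2 down. SDHA, a subunit of complex II, stood at 431 ± 41.8 with DMSO and 306 ± 8.78 CPM with importazole (SD, n = 3), and NDUFA5, of complex I, at 35.6 ± 1.28 and 55.4 ± 5.77 CPM. The ribosomal protein list had a median of -0.44 over 77 members (camera adjusted p = 6.67e-08; adjusted p = 0.611 with an estimated correlation), with 0 members called by edgeR, limma-voom, DESeq2 or limma with quality weights and 0 at an unadjusted edgeR p under 0.05. Without DMSO replicate 3 its median was -0.06 and its call ended (adjusted p = 0.0991, from 1.33e-11 to 0.0991 over the 16 alternatives that tested it).

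The BCL2 family list had a median of -0.20 over 17 members (camera adjusted p = 0.0301; adjusted p = 0.223 with an estimated correlation). BCL2L2 was the 1 member that fell, over all genes tested and adjusted over the list alone alike. The list lay 0.54 higher in DMSO replicate 3, and its median was -0.20 without that library as well, -0.12 with library size scaling and -0.35 with the filter at a mean CPM of at least 5. The call ended without DMSO replicate 2, with quality weights and after the correction for length and GC (adjusted p = 0.0881, 0.0505 and 0.0613; from 0.00700 to 0.0881 over 17 alternatives), where the medians were -0.27, -0.19 and -0.13.

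Lists of the nuclear transport machinery, to which the inhibited receptor belongs, did not pass. The importins had a median of 0.16 over 17 members (camera adjusted p = 0.0774), the nucleoporins 0.14 over 29 (adjusted p = 0.262) and the exportins and Ran cycle genes -0.03 over 15 (adjusted p = 1.000). The importins and nucleoporins lay lower in DMSO replicate 3, by -0.45 and -0.32, and their medians were 0.06 and 0.02 without that library and -0.10 and -0.09 after the correction for length and GC. Without DMSO replicate 2 the importins passed camera, with a median of 0.24 (adjusted p = 0.547 with an estimated correlation).

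Proliferation and damage lists did not pass either: the E2F and G1/S genes had a median of -0.07 over 46 members (camera adjusted p = 0.0774), the G2/M genes 0.01 over 50 (0.836), the p53 targets 0.02 over 26 (0.936), the homologous recombination and Fanconi genes 0.07 over 36 (0.225) and the MYC and ribosome biogenesis genes -0.10 over 41 (0.114). Within the p53 list CDKN1A, the cell cycle inhibitor p21, fell when adjusted over the list alone, from 3.92 ± 0.914 to 1.59 ± 0.131 CPM (SD, n = 3), a call that held without DMSO replicate 2 and was lost without each of the other 5 libraries. MDM2 stood at 35.6 ± 17.3 with DMSO and 71.8 ± 3.14 CPM with importazole, without passing. fry called the E2F list lower (adjusted p = 0.00339). The list also passed camera without DMSO replicate 3 and with quality weights, with a median of -0.08 in both (adjusted p = 0.202 and 0.174 with an estimated correlation), and the MYC list did with quality weights, with a median of -0.11 (adjusted p = 0.466 with an estimated correlation). Without DMSO replicate 3 the medians of the G2/M, p53, recombination and MYC lists were -0.01, 0.05, 0.03 and -0.02. The correction for length and GC turned the G2/M, p53 and recombination medians to -0.02, -0.01 and -0.08, and library size scaling turned the E2F and MYC medians positive.

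The NF-kB targets had a median of -0.15 over 28 members (camera adjusted p = 0.0573), and CCL3, CCL4, CXCL8 and IER3 fell when adjusted over the list alone, a count of 1 to 3 with a library left out (2 without DMSO replicate 3), in which CCL3 was always included. The heat shock genes had a median of -0.15 over 22 (0.0573). Without DMSO replicate 3 both lists passed camera, with medians of -0.04 for NF-kB and -0.11 for heat shock (adjusted p = 0.410 and 0.564 with an estimated correlation). Both also passed without DMSO replicate 2 (medians -0.28 and -0.19; adjusted p = 0.295 for each with an estimated correlation) and without IPZ replicate 2 (medians -0.19 and -0.15; adjusted p = 0.376 and 0.562 with an estimated correlation), and with quality weights (medians -0.18 and -0.15; adjusted p = 0.240 and 0.345 with an estimated correlation). The heat shock list passed without mitochondrial and ribosomal protein genes too, with a median of -0.15 (adjusted p = 0.481 with an estimated correlation).

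The remaining lists did not pass camera with all 6 libraries. The NRF2 targets had a median of -0.17 over 21 (camera adjusted p = 0.427), the aryl hydrocarbon receptor targets 0.11 over 12 (0.836), the lysosome and autophagy genes -0.03 over 38 (0.936) and the mitochondrially encoded genes -0.05 over 13 (0.796). Without DMSO replicate 3 these 4 medians were -0.05, -0.06, 0.02 and 0.04. The mitochondrially encoded genes passed camera without DMSO replicate 2, without IPZ replicate 2 and with quality weights, with medians of -0.29, -0.32 and -0.30 (adjusted p = 0.645, 0.681 and 0.602 with an estimated correlation). The neutrophil maturation genes had a median of -0.28 over 20 (0.117), with TREM1 and MCEMP1 fallen adjusted over the list alone, and the retinoic acid targets -0.27 over 15 (0.102), with DHRS9 and DHRS3 fallen in the same way. Neither neutrophil gene passed without IPZ replicate 1 or 3, and neither retinoic acid target without DMSO replicate 1 or IPZ replicate 1. These lists lay 0.34 and 0.51 higher in DMSO replicate 3, and their medians were -0.08 and -0.08 without that library and 0.06 and -0.01 after the correction for length and GC. Without DMSO replicate 2 the retinoic acid targets passed camera with a median of -0.35 (adjusted p = 0.295 with an estimated correlation). The replication-dependent histones had a median of -0.28 over 14 (0.836), the erythroid and megakaryocyte markers -0.49 over 9 (0.0774) and the epithelial and fibroblast markers -0.56 over 5 (0.0573). These 3 lists lay 0.56, 0.53 and 0.61 higher in DMSO replicate 3, and their medians were -0.13, -0.24 and -0.26 without that library. The histones passed camera without a filter on low counts, with a median of -0.47 (adjusted p = 0.296 with an estimated correlation), and the epithelial and fibroblast markers without IPZ replicate 1, with a median of -0.57 (adjusted p = 0.310 with an estimated correlation) and with a median turned positive without a filter. Among the latter PDGFRB, a growth factor receptor of fibroblasts and pericytes, fell when adjusted over the list alone (log2 fold change -2.22, SE 0.35; edgeR adjusted p = 0.00188 over the list alone and 0.168 over all genes), also with each library left out in turn. For the exportins, p53 targets and aryl hydrocarbon receptor targets the mean had the opposite sign to the median.

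**Figure D4:**
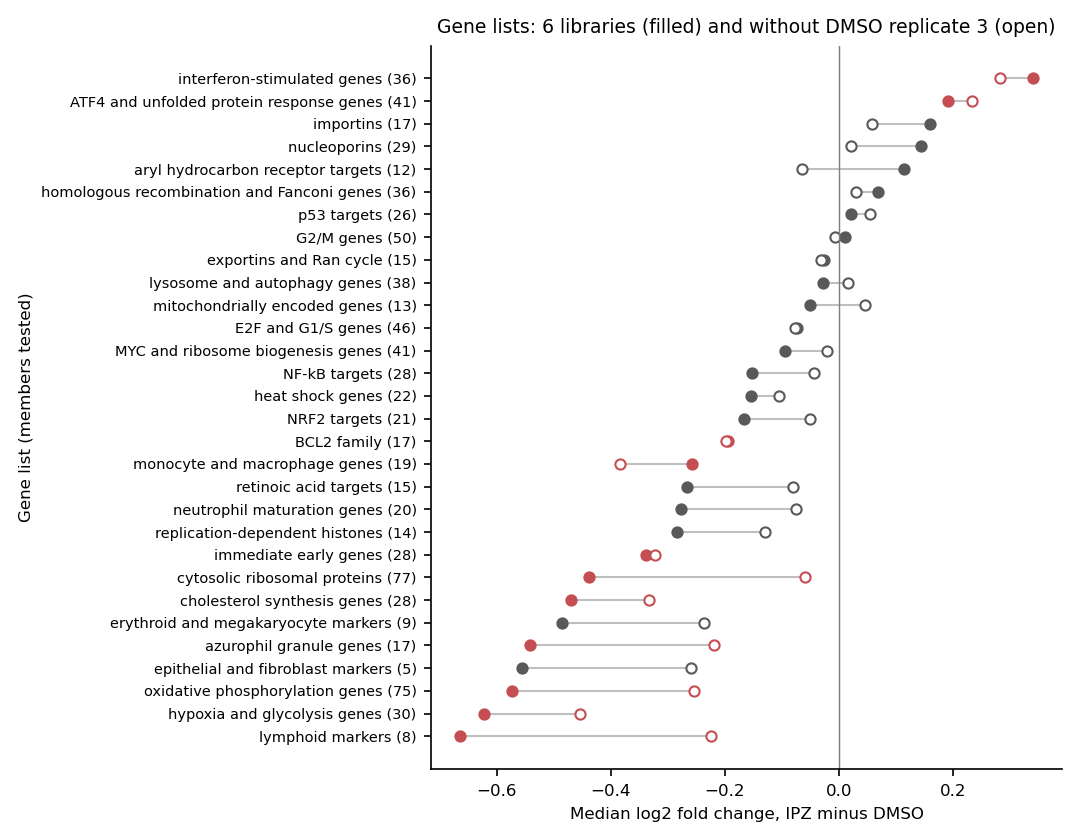
Median log2 fold change (IPZ minus DMSO) of the 30 gene lists, with the number of members tested in parentheses; filled points use all 6 libraries and open points leave out DMSO replicate 3, and red marks the 11 lists past the camera threshold with all 6. The oxidative phosphorylation, azurophil granule, lymphoid and ribosomal protein medians move toward 0 without that library, as does the hypoxia and glycolysis median, from -0.62 to -0.45.

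Among the 30 lists, 11 passed camera's test at its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.101 and 6 lists had an unadjusted p under 0.05; fry, which asks whether a list's genes move one way on balance, called 10. These were the hypoxia, cholesterol, ATF4, interferon, immediate early, monocyte and BCL2 family lists and, beside camera's 11, the E2F, erythroid and epithelial lists, but not the oxidative phosphorylation, ribosomal protein, azurophil granule or lymphoid lists (fry adjusted p = 0.248, 0.453, 0.158 and 0.06996). Among the 11 lists, the estimated correlation was highest for the ribosomal protein, oxidative phosphorylation and azurophil granule lists, at 0.92, 0.76 and 0.38. It lay below the preset 0.01 for the cholesterol, interferon, BCL2 family and monocyte lists, at -0.015, -0.011, -0.020 and -0.004. For those lists the lost call cannot be laid to a correlation above the preset. Of 57 list members past the threshold over their list alone, 13 were past it with each of the 6 libraries left out in turn. Camera also called 4 to 9 lists in the other 9 ways of splitting the 6 libraries into groups of 3. Each of these splits sets mostly DMSO against mostly IPZ libraries, so it still holds part of the treatment difference. Their calls are therefore no baseline for chance.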

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

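The robust fit, the quality weights and the length and GC correction were chosen after seeing the data. The main count of 8 genes, all changed by at least 2-fold, was 8 with RLE, upper quartile or library size scaling, the robust fit and the fit without mitochondrial and ribosomal protein genes, and 10 without a filter or with limma-voom. It was 5 with a mean CPM of at least 5 (H2BC9 and ENSG00000257065 were not tested there, and MEX3C was tested and lost its call; the cause was not tested), 135 with DESeq2 (88 by at least 2-fold; 1483 adjusted p stayed NA), 823 with quality weights (223 by at least 2-fold) and 19 with the length and GC correction (17 by at least 2-fold); the cause was not tested. Leaving out 1 library gave 3 to 20 genes, all by at least 2-fold: 20 without DMSO replicate 3, 12 without DMSO replicate 2, 5 without DMSO replicate 1, and 3, 4 and 5 without IPZ replicates 1, 2 and 3. The share of rises among calls was 62.5% in the main test, 50% with library size scaling, no filter or limma-voom, 37.8% with DESeq2, 36.8% after the length and GC correction, 40%, 66.7% and 50% without DMSO replicates 1, 2 and 3 and 33.3%, 25% and 40% without IPZ replicates 1, 2 and 3. The main 11 lists became 8 to 15 over the other camera fits (11 to 15 when 1 library was left out), 10 with fry and 0 with an estimated correlation, where the lowest adjusted p was 0.101. With the replicate number as a block, 6 genes were called, the 8 less C3 and NCK2 (edgeR adjusted p = 0.0571 and 0.0975), and 11 lists; deviations of libraries with the same number correlated at -0.08, 0.07 and 0.12, so the numbers were not taken to pair the samples. KPNB1 passed under no alternative, with log2 fold changes from -0.16 to 0.19, and no called gene or list changed sign. Over all genes named or listed for naming, 2459 values under an alternative kept their side of the threshold, 145 passed it that had not and 23 no longer passed it; for single lists these numbers were 520, 22 and 22. Depth limits the lowest genes, such as ENSG00000257065 with 3 counts over the IPZ libraries.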

Other observations

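The tests of depth and of cells of another lineage in DMSO replicate 3, the count of called genes with no overlapping exon, the summed counts at BCL2L2 and the fit of the hypoxia list without DMSO replicate 3 were chosen only after the result was seen, as were the genes of the first paragraphs here. MT1X, MT2A, MT1E and MT1G, which encode metallothioneins, small zinc-binding and copper-binding proteins, passed the threshold by DESeq2 as single genes. No list of such genes was fixed or tested. The main edgeR test with all 6 libraries called none of the genes named in this and the next paragraph. MT1X went from 31.2 ± 10.8 to 9.63 ± 0.1599 CPM (SD, n = 3; DESeq2 adjusted p = 2.17e-06, up to 0.666 over 18 alternatives) and MT2A from 152 ± 62.7 to 58.7 ± 2.95 CPM (DESeq2 adjusted p = 0.00177, up to 0.666). MT1E went from 16.996 ± 7.10 to 5.27 ± 0.376 CPM and MT1G from 15.8 ± 2.93 to 5.90 ± 1.15 CPM (DESeq2 adjusted p = 9.77e-05 and 2.73e-05, both up to 0.666). These genes are close paralogs, so how reads were divided among them is uncertain. Each stood highest in DMSO replicate 3, MT2A at 223 CPM against 127 and 105 CPM in DMSO replicates 1 and 2. By edgeR the log2 fold change without that library was -1.40 for MT1X, -0.98 for MT2A, -1.29 for MT1E and -1.27 for MT1G. With all 6 libraries it was -1.70, -1.37, -1.69 and -1.42. SLC30A6, a zinc transporter, rose from 15.9 ± 2.96 to 35.2 ± 1.34 CPM (DESeq2 adjusted p = 1.83e-05, up to 0.666).

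Other single genes passed the threshold by DESeq2. The chemokine gene CCL3 went from 3.32 ± 0.618 to 0.627 ± 0.134 CPM (SD, n = 3, DESeq2 adjusted p = 4.30e-08, up to 0.346 over 17 alternatives). Its close paralog CCL3L3 went from 5.02 ± 1.04 to 1.31 ± 0.109 CPM (DESeq2 adjusted p = 1.57e-07, up to 0.459 over 17). How reads were divided between CCL3 and CCL3L3 is uncertain. The chemokine gene CXCL8 went from 24.1 ± 6.41 to 10.2 ± 1.43 CPM (DESeq2 adjusted p = 0.00138, up to 0.666 over 18). FCGR2B, an inhibitory Fc receptor with a close paralog, went from 3.89 ± 1.26 to 0.496 ± 0.247 CPM (DESeq2 adjusted p = 5.13e-07, up to 0.666 over 17 alternatives), and TREM1, an activating receptor of neutrophils and monocytes, from 4.70 ± 0.787 to 1.73 ± 0.286 CPM (DESeq2 adjusted p = 2.08e-04, up to 0.631 over 17). ABCA1, the cholesterol efflux pump, rose from 64.4 ± 37.4 to 199 ± 17.3 CPM (DESeq2 adjusted p = 0.0115, from 0.00754 to 0.666 over 18 alternatives).

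DMSO replicate 3 stood apart from the other 5 libraries, and low depth is argued against, since IPZ replicate 2 held fewer counts (25068847 against 34319318) and lay with the others on the first component. Lymphoid, erythroid or epithelial cells are argued against as the whole of it, since the azurophil granule genes, which NB-4 itself expresses, lay 1.00 (bootstrap SE 0.18, log2) higher in this library, where foreign cells would dilute them. A smaller contribution of such cells stays open: the lymphoid, erythroid and epithelial lists lay 0.96 (bootstrap SE 0.30), 0.53 (SE 0.30) and 0.61 (SE 0.32) higher, and TRAC, KRT18, GATA1, CD79B and GP1BB stood at 65.0, 36.7, 35.1, 26.3 and 15.4 CPM against at most 51.3, 22.2, 21.6, 16.8 and 8.64 CPM in the others, though TFRC, EPCAM and EPOR, at 136, 9.9997 and 5.94 CPM, lay within the range of the others (84.0 to 248, 8.79 to 11.9 and 4.38 to 6.80 CPM). RNA from other myeloid cells stays open too, since 1 gene stood at 5 CPM or more in this library and under 0.5 in each other library, against 0 in any other library. A candidate explanation is a bias with transcript length in amplification or RNA quality (Spearman rho = -0.55 across genes, the next in size being 0.31); no biological explanation was tested, as the labels give none for a single library.

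The called genes changed by large folds, some with little spread, and a division of reads between overlapping genes might produce this. The 5 called genes that share no exon with a listed gene have, by definition, no listed gene to divide reads with in this way. Unlisted genes and near-identical copies, as for H2BC9, were not tested and stay open. Over all tested genes such a division is argued against as a general cause of low unadjusted p-values. Exon-sharing genes reached an unadjusted p under 0.05 no more often than others (10.8% against 11.1%, ratio 0.97, Fisher's exact test p = 0.565). These shares hold changes of any size, so they do not show whether large folds were more frequent among exon-sharing genes. A division of counted reads is argued against for BCL2L2 as the whole change. The sum of BCL2L2 and its overlapping genes fell from 47.9 ± 4.54 to 24.1 ± 5.24 CPM (SD, n = 3), a log2 change of -0.99. Reads left uncounted because they overlap several genes would be missing from that sum. Their treatment is not given, so a change in such reads stays open. For ENSG00000272772 and ENSG00000257065 a division of reads cannot be told apart from a change in level, because their partners dominate the sum. The median size of the log2 change of the sum over the 3 exon-sharing genes was 0.25. While ENSG00000272772 rose, its partners together went from 307 ± 43.1 with DMSO to 223 ± 2.85 CPM with importazole (SD, n = 3). While ENSG00000257065 fell, its partners went from 77.2 ± 11.7 to 90.2 ± 1.68 CPM. The effect of importazole stays open for all 8, as the design compares no other compound. With 10 splits of the 6 libraries no share under 0.05 can be reached, and the other splits hold part of the treatment difference too. The real split called 8 genes (8 by at least 2-fold) and the highest other split 1 (1 by at least 2-fold).

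The hypoxia and glycolysis genes lay lower after importazole. The tables argue against a trend with transcript length and GC as the whole of it, since the median was -0.60 after that correction, and against DMSO replicate 3 alone, since it was -0.45 without that library; camera's adjusted p at the preset correlation was at most 2.58e-07 over 17 alternatives, but with an estimated correlation the call was lost (adjusted p = 0.101, and 0.0622 to 0.411 over these alternatives). A shift of abundant genes is argued against too, since the median lay at percentile 0 of 10000 random lists matched on mean expression. In the 10 splits the real one gave the lowest p for the list (1 of 10, too few for a share under 0.05), with a median of -0.62 against 0.35 in size for the highest other, although 6 of the 9 others also passed camera's threshold. Those others hold part of the treatment difference, so their calls do not measure chance. A lower hypoxia and glycolysis programme with importazole is thus a hypothesis found and tested on the same libraries, which oxygen, cell density or medium at harvest could also produce and for which the labels give no value.

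By camera 11 lists passed in the real split and at most 9 in another, where 10 splits allow no share under 0.05. Every other split keeps part of the treatment difference, so in general a pass there can come from it or from the spread between libraries. For ribosomal protein and oxidative phosphorylation, treatment is argued against as the source where DMSO replicates 1 and 2 were grouped with 1 IPZ library. The other group, with DMSO replicate 3 and most IPZ libraries, lay higher, by ribosomal protein medians of 0.32, 0.45 and 0.34 (IPZ replicates 1, 2 and 3). Oxidative phosphorylation medians were 0.25, 0.36 and 0.23, while the real split gave lower values with importazole. The ribosomal protein and oxidative phosphorylation lists passed in all 9 other splits, the azurophil granule list in 6 and the ATF4 list in 4, while the monocyte, lymphoid and BCL2 family lists passed in 0 of them; the interferon and immediate early lists passed in 2 each and the cholesterol list in 3. A p as low as the real one or lower came, the real split included, from 8 of the 10 splits for the ribosomal protein list, 3 for oxidative phosphorylation and 2 for ATF4, and from the real split alone for each of the other 8 called lists.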
